A study of Mus musculus with 11 samples.

How the data were processed

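The deposited table held one value per probe set and array for 22690 probe sets on 11 arrays, one per mouse, and no other per-sample columns were present. Total liver RNA was reverse transcribed from a poly-dT primer and labelled with biotin by in vitro transcription, per the labels' protocols. The values are linear intensity values (signal) made with MAS5 by the authors, per the submitters' processing notes, which give no version. MAS5 summarises the probe pairs of a probe set on one array at a time and scales each array, so arrays are comparable in overall brightness and not in the shape of their distribution. The mean signal after leaving out the lowest and highest 2% was 500.251 to 500.285 on each array, so no further scaling was applied. The deposited intensity values came without detection calls here, so signal over background was not judged per probe set, and 1385 values under a signal of 1 were set to 1 before log2.

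Groups were taken from the sample titles: wild type on a normal diet (n = 3), wild type on a high-fat diet (n = 4) and Akt1 double transgenic on a high-fat diet (n = 4). Gene symbols came from the platform annotation. Of the probe sets, 20380 had 1 symbol, 691 several and 1555 none, and 64 were manufacturer controls. Through Entrez identifiers 20351 of those with 1 symbol were found in a RefSeq gene table (GRCm38.p6), and 0 symbols changed. The platform annotation gives no genome build, so no coordinates are reported. Control probe sets and probe sets with several symbols or none were left out. Probe sets in the lowest 40% by mean log2 signal (under a signal of about 53.0) were left out, and the probe set of the highest mean stood for each gene, which left 7924 genes.

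Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with all 11 arrays in one fit and a mean per group, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. Errors beside log2 differences are limma's moderated standard errors, and fold changes are on the log2 scale with that floor. Lists were tested with limma's camera at its preset correlation of 0.01, Benjamini-Hochberg adjusted over lists. There were 33 lists of liver metabolism, hormone response, immunity, stress, growth, clock and cell type markers, and the 30 with at least 5 measured genes were tested. Each passing list had a median, mean and test of the same sign. Camera with an estimated correlation and the rotation test fry were alternatives. Fry asks whether a list's genes move, on balance, one way, without comparing them with other genes. None of the calls held with an estimated correlation. By fry, 0 lists passed for diet and 4 for the transgenic mice: acute phase proteins and cell cycle (fry adjusted p = 0.00530 each), oxidative phosphorylation (0.00760) and NRF2 antioxidant genes (0.0206).

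The limma and camera tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from additions named as such. The rule took the 8 largest rises and 8 largest falls among genes past the threshold without overlap between arrays, filled up with the smallest p where fewer passed. From each passing list it took up to 3 members of largest change past the threshold, or the 2 of smallest p, given as values. For transgenic mice against the normal diet it took 4 in each direction. Other probe sets of named genes, 55 for 27 gene and comparison pairs, had the same sign in 47, and 1 with an unadjusted p under 0.05 disagreed (Rps24 for diet).

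On simulated data with the spread of these arrays and independent noise, in a single run each, 0 genes were called in unchanged data for each comparison. Of 100 genes changed 2-fold, 64% were recovered for diet, 63% for the Akt1 comparison and 71% for transgenic mice against the normal diet. Of 100 genes changed 4-fold, 92%, 93% and 94% were recovered, over 7924 genes in each case. False calls numbered 10, 5 and 10. The 2-fold and 4-fold genes were changed together, which eases the adjusted threshold for the 2-fold genes. These shares therefore need not hold where few genes change.

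Alternatives were quantile normalization, log2(signal + 32), no filter or a 60% filter on dim probe sets, all probe sets, eBayes without trend or robust, array weights, only the groups compared in the fit, the replicate number as a block, and leaving out each array in turn. After the data were seen, fits without transgenic arrays 3 and 4 and without transgenic arrays 1 and 2 were added, as were an exact permutation test of list scores and the list test for transgenic mice against the normal diet. Shared control arrays were handled by 100 simulations of unchanged groups and by splitting the shared arrays.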

Results

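Liver RNA was profiled from 11 male mice of a mixed genetic background, one oligonucleotide array per mouse, to ask how a high-fat diet and Akt1-driven muscle growth affect gene expression in the liver. The normal diet was given to wild-type mice alone (3 arrays), and the high-fat diet to wild-type mice (4 arrays) and to mice carrying the Akt1 double transgene (4 arrays). Akt1 is a protein kinase of insulin and growth factor signalling, and the labels mark muscle hypertrophy in the transgenic mice alone. All 3 groups received doxycycline, the drug used to switch on inducible transgenes, for 3 weeks. Each array reported 22690 probe sets as a linear signal scaled to a trimmed mean near 500, and median signals lay between 97.2 and 118 per array. Spearman correlations between pairs of arrays ranged from 0.935 to 0.956. Transgenic arrays 3 and 4 had top signals of 42426 and 43273, above the range of 27780 to 35450 in the other 9 arrays. Their signals at percentile 2 were higher as well, at 2.2 and 2.3 against 1.4 to 1.8. Transgenic array 3 also had a mean poly-A spike signal of 77.5 (203 to 339 in the other 10), the highest Gapdh 3'/5' ratio, 0.823 (0.669 to 0.768 in the others), and the lowest mean Spearman correlation with other arrays, 0.940. The number of arrays limits the precision of every value.

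Akt1 itself was measured in the liver by 2 probe sets. The brighter had mean signals of 415 ± 58.6 (SD, n = 3) in normal-diet mice, 467 ± 41.3 (SD, n = 4) in wild-type high-fat mice and 496 ± 70.5 (SD, n = 4) in transgenic mice. The dimmer had 240 ± 38.4, 210 ± 16.0 and 238 ± 73.1. The difference between transgenic and wild-type high-fat mice was 0.080 ± 0.13 (log2, SE) at the brighter and 0.13 ± 0.20 at the dimmer. Neither passed in limma's test, with adjusted p of 0.874 and 0.867 over all probe sets. Per array, the brighter ranged from 433.9 to 585.3 in transgenic mice and from 420.6 to 512.6 in wild-type high-fat mice.

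The high-fat diet was first compared with the normal diet in wild-type mice, and no single gene passed. Among genes of secreted acute phase proteins, Lcn2 and Saa1 had wide gaps. The median log2 difference over the 27 measured acute phase genes was 0.15. Lcn2, which encodes lipocalin 2, had a signal of 601 ± 389 (SD, n = 4) on the high-fat diet against 64.2 ± 6.81 (SD, n = 3), a log2 difference of 2.97 ± 0.62 (SE). Saa1, which encodes serum amyloid A, had 4648 ± 2834 against 1189 ± 292, a log2 difference of 1.82 ± 0.40. Lower values on the high-fat diet included Me1, the cytosolic malic enzyme that supplies NADPH for lipid synthesis, at -1.29 ± 0.26, and Rgs16, a regulator of G protein signalling, at -2.14 ± 0.40.

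Of 7924 genes tested, 0 passed an adjusted p of 0.05 in limma's fit, and 556 had an unadjusted p under 0.05 where chance gives 396.2. With array weights 1 gene passed, and there were 2 with the replicate number as a block and 2 without wild-type normal-diet array 2. The smallest adjusted p, 0.0705, belonged to Krt8, a keratin of epithelial cells, with a log2 difference of 0.71 ± 0.10 and every high-fat array above every normal-diet array. The other genes of smallest p with higher values were Hsd3b3 (1.12), Tmem184c (0.86), Mterf2 (1.19), Coq7 (0.59) and Stard3nl (0.69). Those with lower values were Slco2a1 (-1.11), Dnase2a (-1.59), Ehbp1 (-0.79), Ddx21 (-0.77), Tkfc (-1.15) and Btd (-0.57), all in log2 units. None of these passed.

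Among 30 gene lists, 7 shifted on the high-fat diet in limma's camera test with its preset correlation, 5 towards higher and 2 towards lower signal. The number was 4 without wild-type normal-diet array 1, where the bile duct list had a camera adjusted p of 0.128, and 25 of 35 splits of the 7 arrays, the real one included, gave as many lists. Acute phase proteins had a mean shift of 0.41 over 27 measured genes (camera adjusted p = 0.000138, and adjusted p = 0.686 with an estimated correlation). None of them passed over all genes, and 4 were higher when adjusted over the list alone. Kupffer cell and macrophage markers had a mean shift of 0.56 over 18 genes (camera adjusted p = 5.75e-05, and adjusted p = 0.835 with an estimated correlation), with Aif1 at 1.13 ± 0.37 and the folate receptor Folr2 at 0.93 ± 0.34. Bile duct cell markers shifted by 0.39 over 9 genes (camera adjusted p = 0.00216, and adjusted p = 0.192 with an estimated correlation), and 2 were higher when adjusted over the list alone. Their examples were the keratins Krt8, which hepatocytes also make, and Krt23, the latter at 1.77 ± 0.52.

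Secreted proteins of hepatocytes shifted by 0.13 over 27 genes on the high-fat diet (camera adjusted p = 0.00132, and adjusted p = 0.835 with an estimated correlation), and 1 was higher when adjusted over the list alone. Apoc2, a lipoprotein component, was at 0.50 ± 0.12 and Otc, a urea cycle enzyme, at 0.35 ± 0.14. Stellate cell and fibrosis markers shifted by 0.22 over 18 genes (camera adjusted p = 0.0371, and adjusted p = 0.835 with an estimated correlation), with the collagen gene Col1a2 at 0.65 ± 0.24 and Dcn at 0.32 ± 0.14. Ribosomal proteins shifted by -0.12 over 28 genes (camera adjusted p = 5.75e-05, and adjusted p = 0.835 with an estimated correlation), with Rps24 at -0.33 ± 0.10 and Rps19 at -0.28 ± 0.10. A dim probe set for Rps24 had the opposite sign, at 2.20 with an unadjusted limma p under 0.05. Liver endothelial cell markers shifted by -0.18 over 21 genes (camera adjusted p = 0.00144, and adjusted p = 0.835 with an estimated correlation), with Ehd3 at -0.52 ± 0.14 and the scavenger receptor Stab1 at -0.35 ± 0.15. In the stellate, Kupffer, ribosomal and endothelial lists 0 genes passed when adjusted over the list alone. Without wild-type normal-diet array 1 the stellate and endothelial lists had a camera adjusted p of 0.128, without array 2 the stellate list had 0.105 and hepatocyte secreted proteins 0.331, and without wild-type high-fat arrays 2 and 4 in turn the stellate list had 0.457 and 0.0653. In an exact two-sided permutation test of list scores, added after the results were seen, p for diet was 0.0286 for hepatocyte secreted proteins, 0.0571 for acute phase proteins, 0.0857 for bile duct markers, 0.171 for Kupffer, ribosomal and endothelial lists and 0.429 for stellate markers, and no adjusted p over 30 lists was under 0.429. In the same exact test, p was also 0.0286 for insulin and growth hormone signalling and 0.0571 for glycolysis and glycogen, which camera did not call. The 23 lists that camera did not call, among them cholesterol synthesis, oxidative phosphorylation and circadian clock, had camera adjusted p from 0.0657 to 0.993. Of these, interferon response (0.23, camera adjusted p = 0.0657) passed without wild-type normal-diet array 2 (0.49, 0.000123) or wild-type high-fat array 1 (0.35, 0.00376) or 4 (0.42, 0.000386), and with the replicate number as a block (0.33, 0.00125). Without wild-type high-fat array 2, fatty acid synthesis (camera adjusted p = 0.0386), lipid uptake and droplet storage (0.0336) and bile acid synthesis (0.0336) passed, and xenobiotic metabolism did without array 3 (0.0177) and with the block (-0.22, 0.0139). With no filter on dim probe sets, interferon response (0.32, camera adjusted p = 0.0233) and skeletal muscle markers (0.57, 0.0368) passed.

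In transgenic mice on the high-fat diet, 4 of 27 acute phase genes and 2 of 16 cell cycle genes rose against wild-type mice on the same diet, and both lists shifted in camera with its preset correlation, though not with an estimated one (adjusted p = 0.111 each with an estimated correlation). Prtn3, which encodes proteinase 3, a serine protease known from neutrophil granules, rose from a signal of 19.4 ± 16.8 to 604 ± 563 (SD, n = 4 each). The wild-type signal lay under the limit for dim probe sets, about 53.0, so the fitted log2 difference of 4.89 ± 0.75 (SE) depends on values near the background. Saa1 rose 4.21-fold, from 4648 ± 2834 to 18366 ± 6519. Fgl1, a fibrinogen-like protein secreted by hepatocytes, rose 3.23-fold, from 5952 ± 1915 to 18605 ± 2761. Gsta2, a glutathione S-transferase, was 4.41-fold lower, at 339 ± 250 against 1356 ± 577, and Cyp4a12a, a fatty acid hydroxylase that male mice express more than females, fell by 1.32 on the log2 scale, at 3721 ± 1652 against 8749 ± 897.

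**Figure D1:**
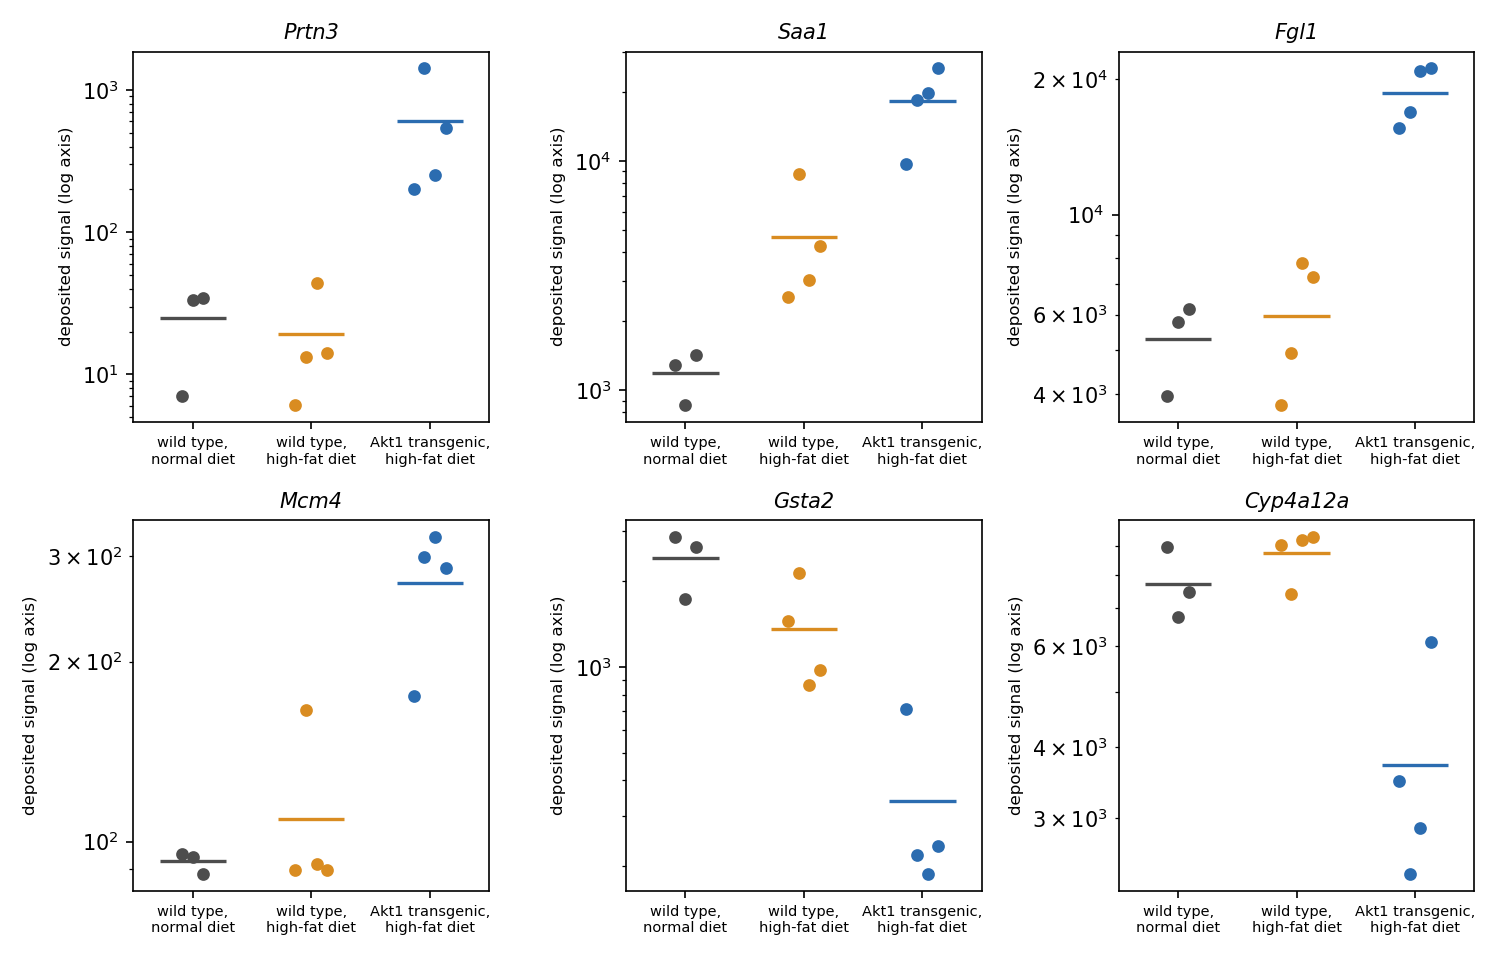
Deposited signal (vertical log axis, arbitrary units) of 6 genes in each liver, by group; points are mice and horizontal lines are group means. Prtn3, Saa1, Fgl1 and Mcm4 lay higher, and Gsta2 and Cyp4a12a lower, in all 4 transgenic arrays than in all 4 wild-type arrays on the high-fat diet, with mean signals for Prtn3 of 604 against 19.4.

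Limma called 29 of 7924 genes, 18 higher and 11 lower, and 1085 genes had an unadjusted p under 0.05 where chance gives 396.2. For 666 genes (8.40%) the arrays of both groups did not overlap, where chance gives 2.86%. The number called was 0, 64, 1 and 6 without wild-type high-fat arrays 1, 2, 3 and 4 in turn, and 56, 6, 3 and 2 without transgenic arrays 1, 2, 3 and 4. It was 0 without an intensity trend in the variance (eBayes), 12 without a filter, 8 with only these groups in the fit, and 4 without transgenic arrays 3 and 4 together. The other top rises were Ung, a uracil-DNA glycosylase of base excision repair (log2 1.91 ± 0.34, limma adjusted p = 0.0461), the cytochrome P450 Cyp3a13 (1.81 ± 0.34, 0.0488), the co-chaperone Dnajc12 (1.64 ± 0.29, 0.0461), the replication licensing factor Cdt1 (1.57 ± 0.25, 0.0370) and the interleukin-1 receptor antagonist Il1rn (1.51 ± 0.26, 0.0436). The limma adjusted p was 0.0317 for Prtn3, 0.0465 for Saa1, 0.025 for Fgl1, 0.0482 for Gsta2 and 0.0436 for Cyp4a12a. The other top falls were the membrane peptidase Mme (-1.24 ± 0.23), the acetyltransferase Nat8 (-1.23 ± 0.21), the carbonic anhydrase Car1 (-1.01 ± 0.16), the carboxylesterases Ces1e (-0.95 ± 0.16) and Ces1d (-0.81 ± 0.14), and Ropn1l (-0.76 ± 0.12), with limma adjusted p from 0.0317 to 0.0482. The rule that chose these genes required every transgenic array to lie beyond every wild-type array on the same diet, so this is no further support.

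**Figure D2:**
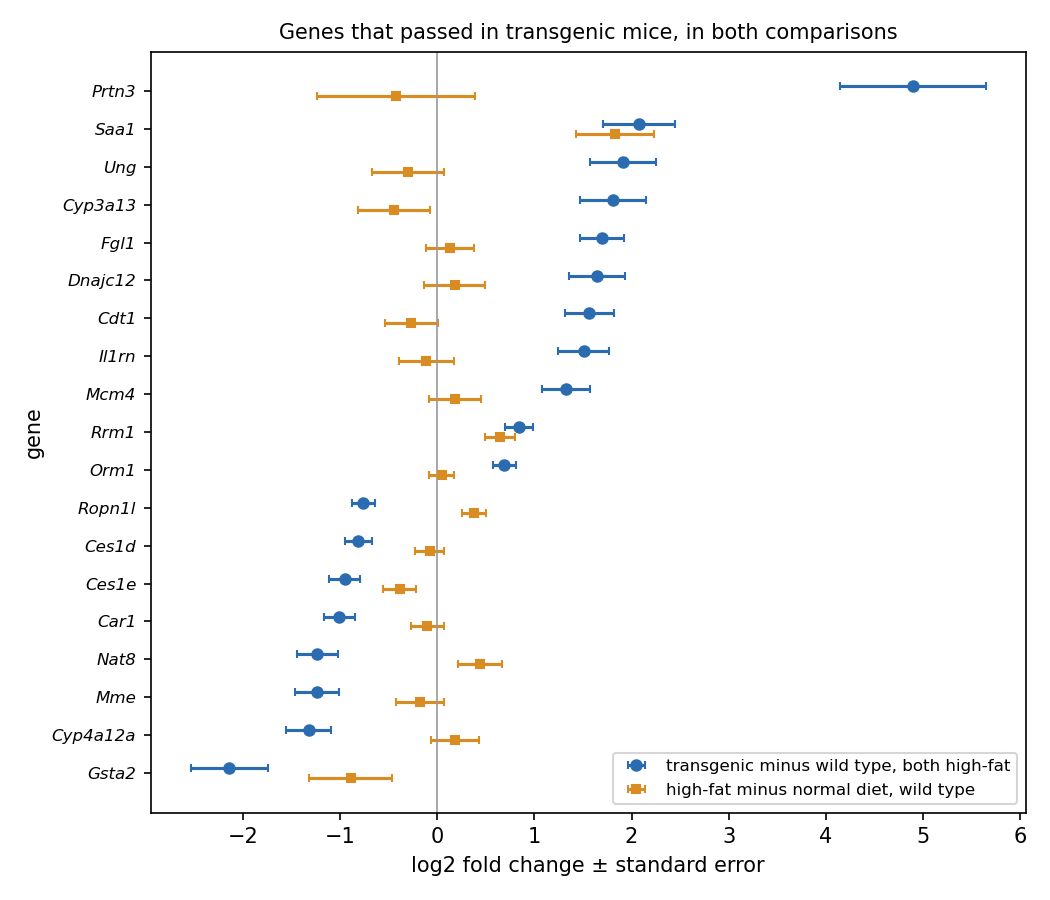
Log2 fold change with its standard error for the 19 named genes that passed in the transgenic mice, for transgenic against wild-type mice on the high-fat diet (circles) and for the high-fat against the normal diet in wild-type mice (squares). Prtn3 was at 4.89 in the first comparison, a value that depends on wild-type signal under the limit for dim probe sets, and Gsta2 was at -2.14, while no gene passed in the second.

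Acute phase proteins had a mean shift of 0.86 over 27 measured genes in the transgenic mice (camera adjusted p = 2.14e-15, and adjusted p = 0.111 with an estimated correlation). Of these, 4 rose over all genes tested, 18 were higher when adjusted over the list alone, and none was lower. Besides Saa1 and Il1rn, the orosomucoid gene Orm1 rose by 0.69 ± 0.12 and Itih3, which encodes an inter-alpha-trypsin inhibitor heavy chain and was chosen after its values were seen, by 0.65 ± 0.089. The list score lay between 0.92 and 1.58 in the transgenic arrays and between 0.14 and 0.51 in the wild-type high-fat arrays, where 0 is the mean on the normal diet. Cell cycle genes had a mean shift of 0.96 over 16 measured genes (camera adjusted p = 8.15e-09, and adjusted p = 0.111 with an estimated correlation). Mcm4, a subunit of the replicative helicase (1.33 ± 0.24), and Rrm1, a subunit of ribonucleotide reductase (0.84 ± 0.14), rose over all genes, and 10 were higher when adjusted over the list alone. An exact two-sided permutation test of the arrays, added after the result was seen, gave p = 0.0286 for each of these scores, the smallest that 4 arrays against 4 allow, and 0.107 after adjustment over 30 lists. The same p was reached by oxidative phosphorylation, NRF2 antioxidant genes, endoplasmic reticulum stress, gluconeogenesis and FOXO1 targets, and by insulin and growth hormone signalling and circadian clock, which camera did not call. It was not reached by the other 9 lists that camera called, such as cholesterol synthesis (0.143), interferon response (0.229) and Kupffer cell markers (0.286) in that exact test. The permutation ignored replicate numbers, although deviations of same-numbered arrays had correlations of 0.0842 to 0.292 in this comparison. It may therefore miss shifts between arrays of the same number.

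**Figure D3:**
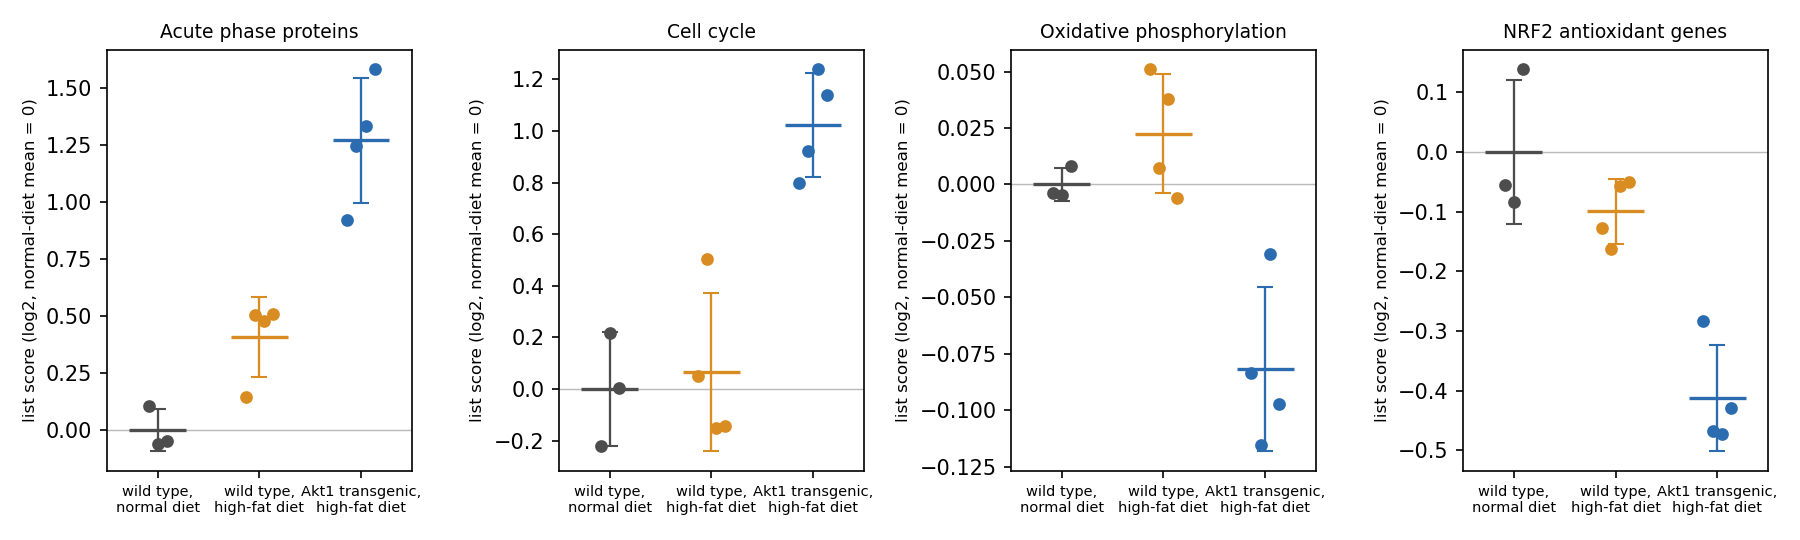
List score (mean log2 signal of a list's measured genes, with the normal-diet mean set to 0) of 4 gene lists in each liver; points are mice, horizontal lines group means and bars their SD. Transgenic means were 1.27 for acute phase proteins, 1.03 for cell cycle, -0.082 for oxidative phosphorylation and -0.41 for NRF2 antioxidant genes, and vertical axes differ between panels.

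In camera, 15 of 30 lists shifted in the transgenic mice, 10 towards higher and 5 towards lower signal, and 4 of 35 splits of the 8 arrays, the real one included, gave as many. The 5 lower lists were of detoxification, energy and sterol metabolism and male-biased genes. NRF2 antioxidant genes had a mean shift of -0.31 over 24 genes (camera adjusted p = 2.96e-05, and adjusted p = 0.151 with an estimated correlation), where 1 gene, Gsta2, fell over all genes and 8 were lower when adjusted over the list alone. Xenobiotic and drug metabolism shifted by -0.21 over 35 genes (camera adjusted p = 0.000107, and adjusted p = 0.321 with an estimated correlation), with Gsta2 lower and Cyp3a13 higher over all genes, and 9 lower and 2 higher when adjusted over the list alone. Oxidative phosphorylation shifted by -0.10 over 45 genes (camera adjusted p = 2.96e-05, and adjusted p = 0.151 with an estimated correlation). None of its genes passed alone, and 36 of 45 lay below 0, such as Ndufb3 at -0.37 ± 0.10 and Ndufb9 at -0.25 ± 0.07, both subunits of respiratory complex I. Cholesterol synthesis and uptake shifted by -0.44 over 20 genes (camera adjusted p = 2.61e-05, and adjusted p = 0.426 with an estimated correlation), with none passing. Its examples were Hmgcs1 at -0.97 ± 0.29 and Cyp51 at -0.72 ± 0.24, both enzymes of the sterol pathway. Male-biased liver genes shifted by -0.39 over 20 genes (camera adjusted p = 0.0124, and adjusted p = 0.502 with an estimated correlation), where Cyp4a12a fell and 3 were lower when adjusted over the list alone. Its score was -0.96 in transgenic array 3, which had the lowest poly-A spike signal, and -0.12, -0.014 and 0.067 in transgenic arrays 1, 2 and 4. The male-biased list was no longer past the threshold without transgenic array 3 (camera adjusted p = 0.141) or without wild-type high-fat array 1 (0.0902).

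Lists of immune and secretory function were among those with higher signal in camera. Interferon response genes shifted by 0.46 over 21 genes (camera adjusted p = 0.000413, and adjusted p = 0.502 with an estimated correlation), with the peptide transporter Tap1 at 0.71 ± 0.20 and the GTPase Iigp1 at 0.42 ± 0.13. Antigen presentation shifted by 0.31 over 13 genes (camera adjusted p = 0.00573, and adjusted p = 0.321 with an estimated correlation), with H2-D1 at 0.32 ± 0.11, and 2 higher and 1 lower when adjusted over the list alone. Endoplasmic reticulum stress genes shifted by 0.28 over 26 genes (camera adjusted p = 0.000345, and adjusted p = 0.360 with an estimated correlation), with Sdf2l1 at 1.13 ± 0.29 and the chaperone Dnajb11 at 0.48 ± 0.13, and 7 were higher when adjusted over the list alone. Ribosomal proteins shifted by 0.15 over 28 genes (camera adjusted p = 2.13e-05, and adjusted p = 0.426 with an estimated correlation), with Rpl6 at 0.33 ± 0.09 and Rps24 at 0.29 ± 0.09. Gluconeogenesis and FOXO1 targets shifted by 0.33 over 18 genes (camera adjusted p = 0.0134, and adjusted p = 0.321 with an estimated correlation), with Fbp1 at 0.35 ± 0.09 and the aminotransferase Got1 at 1.51 ± 0.44, and 2 were higher when adjusted over the list alone. That list was not past the threshold without wild-type high-fat array 2 (camera adjusted p = 0.0669) or without transgenic arrays 3 and 4 (0.152). None of the genes in these 5 lists passed over all genes tested.

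Hepatocyte secreted proteins shifted by 0.18 over 27 genes in transgenic mice (camera adjusted p = 4.53e-06, and adjusted p = 0.438 with an estimated correlation), with the fibrinogen chain Fgb at 0.36 ± 0.11 and the coagulation factor F9 at 0.26 ± 0.08, and none passed. The arrays with the highest top signals, transgenic 3 and 4, moved with this list, and without them its shift was 0.040 (camera adjusted p = 0.696). After quantile normalization it was 0.036 (0.183). Among markers of other cells, Kupffer cell and macrophage markers shifted by 0.45 over 18 genes (camera adjusted p = 0.00234, and adjusted p = 0.502 with an estimated correlation), with Mpeg1 at 0.98 ± 0.43 and Cd5l at 0.86 ± 0.42. Liver endothelial markers shifted by 0.17 over 21 genes (camera adjusted p = 0.0170, and adjusted p = 0.502 with an estimated correlation), with Gpr182 at 0.56 ± 0.19 and Clec4g at 0.41 ± 0.14. Without transgenic arrays 1 and 2 together, the Kupffer list was at 0.16 (camera adjusted p = 0.419) and the endothelial list at 0.041 (0.537). The Kupffer list missed the threshold without wild-type high-fat array 3 (camera adjusted p = 0.0713) or transgenic array 2 (0.147), and the endothelial list without wild-type high-fat array 3 (0.0647) or 4 (0.0544), or transgenic array 1 (0.108) or 2 (0.0713). Bile duct markers were at -0.30 and stellate markers at -0.0069, and neither passed, except without wild-type high-fat array 4 for bile duct (-0.37, camera adjusted p = 0.0440) and without array 3 for stellate markers (-0.14, 0.0188). The 15 lists that did not pass had camera adjusted p from 0.0674 to 0.976, skeletal muscle and adipocyte markers among them. Of these, fatty acid synthesis passed towards lower signal without wild-type high-fat array 1 (camera adjusted p = 0.0256) or 3 (0.0235) or transgenic array 2 (0.00253), bile acid synthesis without wild-type high-fat array 2 (0.00401) or transgenic array 4 (0.0229), and circadian clock without transgenic array 1 (0.0484) or 4 (0.0441). Peroxisomal and microsomal PPARA targets passed towards lower signal without transgenic array 3 (0.0276). Towards higher signal, mitochondrial fatty acid oxidation passed without transgenic array 1 (0.0240) or 2 (0.0172), as did lipid uptake and droplet storage (0.0240 and 0.0445). Without a filter on dim probe sets, lymphocyte markers passed towards higher signal (0.54, camera adjusted p = 0.0313). Fatty acid synthesis (0.0196), bile acid synthesis (0.0284) and circadian clock (0.0239) then passed towards lower signal. With the filter, markers of neutrophils (2 measured genes), red cells (4) and pancreas acinar cells (4) were too few to test.

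Transgenic mice on the high-fat diet were also set against wild-type mice on the normal diet, a comparison in which diet and genotype differ together. The largest rises without overlap were in the acute phase genes Lcn2, 56.7-fold higher (4538 ± 3004, SD, n = 4, against 64.2 ± 6.81, n = 3), Saa2, higher by 4.32 ± 0.75 (log2, SE), and Saa1, 14.9-fold higher, and in Prtn3, at 604 ± 563 against 25.0 ± 15.6, the latter under the limit for dim probe sets. The largest falls were in Csad, an enzyme of taurine synthesis, at -3.58 ± 0.45 (log2, SE; signal 297 ± 183 against 3063 ± 741), Gsta2 (8.17-fold), the lysosomal nuclease Dnase2a (6.56-fold) and Me1 (5.15-fold). In limma's fit 165 genes passed, 111 higher and 54 lower, with 1451 at an unadjusted p under 0.05. The limma adjusted p was 0.00118 for Lcn2, Saa1, Dnase2a and Me1, 0.0183 for Prtn3, 0.0162 for Saa2, 0.00319 for Csad and 0.00731 for Gsta2. The arrays of both groups did not overlap for any of these 8 genes, which the rule that chose them required. Acute phase proteins rose in 11 of 27 genes and cell cycle genes in 6 of 16 over all genes tested. In camera, run for this comparison after the data were seen, 13 of 30 lists passed with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.0731, for acute phase proteins. The count of 165 genes became 48, 48 and 73 without wild-type normal-diet arrays 1, 2 and 3 in turn. It was 162, 113, 96 and 36 without transgenic arrays 1, 2, 3 and 4 in turn, and 23 without transgenic arrays 3 and 4 together.

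Whether genes moved by the diet moved back in the transgenic mice was examined over all genes. No gene passed in limma for diet, where 556 had an unadjusted p under 0.05, so none could be counted as moved back, and the count of 0 says nothing about reversal. With the replicate number as a block, 2 genes passed for diet and 1 had moved back. The Pearson correlation across genes between the diet and the Akt1 log2 fold changes was -0.130, and genes are not independent replicates. Both comparisons share the wild-type high-fat arrays, which alone gives a negative value. In 100 simulations of unchanged groups the correlation averaged -0.463 (range -0.498 to -0.412). The covariance was -0.0140 against -0.0294 in the simulations, a difference of 0.0154. With the 4 shared arrays split 2 and 2 between the comparisons, the correlation averaged 0.124 over 6 splits (range 0.0281 to 0.220). Both the simulations and the split take arrays as independent, whereas deviations of same-numbered transgenic and wild-type high-fat arrays had a mean correlation of 0.158. Such a shared deviation would also make the split value positive, so no direction is read from it. With all shared arrays in both comparisons, the correlation of -0.130 became -0.166 without wild-type high-fat array 1, -0.255 without array 2, -0.210 without array 3 and -0.199 without array 4. Fewer shared arrays alone make the value more negative, and no simulation was run for these settings. They are therefore not read as reversal.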

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

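The tests of the higher top signals of transgenic arrays 3 and 4, of the neutrophil markers and of the share of hepatocytes were chosen only after the results were seen, and the neutrophil test replaced a first version on Mpo and Elane alone. The matched lists, the neighbouring genes and the splits of the samples were planned before theirs.

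Some arrays stood far from the other 3 of their group in the gap to their nearest neighbour, in 7 of 168 groups of 4 tested, where chance gives about 8.4. Among wild-type mice on the high-fat diet, array 2 had a Mcm4 signal of 165.9 (others 89.5 to 91.8), a Cyp4a12a signal of 7416 (others 9037 to 9322) and a Ces1d signal of 9005 (others 13179 to 14129). Array 4 had an Iigp1 signal of 6722 (others 8583 to 8972), and array 1 an acute phase list score of 0.14 (others 0.48 to 0.51). Among transgenic mice, array 1 had a Gsta2 signal of 712.3 (others 188.2 to 235.1) and array 3 a Clec4g signal of 1659 (others 2307 to 2381).

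Control probe sets for mouse actin and Gapdh, used in no comparison, lay above all normal-diet arrays in some groups. Only higher signal was looked for, over 16 control probe sets, and 6 pairs of probe set and group were flagged. The actin probe sets report the same transcript. The actin 5' probe set averaged 9407 in wild-type mice on the high-fat diet and 10454 in transgenic mice (normal diet 7228 to 8336), and the middle actin probe set 11344 and 11839 (normal diet 8572 to 9816). In transgenic mice the actin 3' probe set averaged 16292 (normal diet 11863 to 14341) and the middle Gapdh probe set 15064 (normal diet 12397 to 13068).

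Other splits of the same arrays were fitted for each count. For the Akt1 comparison, 1 of 35 splits, the real one, gave as many as 29 genes, and the highest other gave 2. For transgenic mice against the normal diet it was also 1 of 35 splits, with 165 genes against 17. With 35 splits, 1 in 35 is the smallest share that can be reached, and the splits take arrays as independent. Chance is therefore not excluded for either count. For diet genes the real count was 0, which all 35 splits reach by construction (highest other 3), so the splits decide nothing there. For gene lists chance cannot be excluded either: 25 of 35 splits gave as many as the 7 lists of the diet comparison (highest other 15), and 4 of 35 gave as many as the 15 lists of the Akt1 comparison (highest other 17).

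Acute phase proteins were higher in the transgenic mice by a mean log2 of 0.86 (camera adjusted p = 0.111 with an estimated correlation). Without transgenic arrays 3 and 4, whose top signals were higher, the shift was still 0.67 and the list passed camera with its preset correlation. Its median of 0.65 lay above all of 10000 lists matched on mean signal (percentile 100, highest matched median 0.21), which argues against a general rise of bright probe sets. Hepatocyte secreted proteins behaved otherwise, with a shift of 0.040 without transgenic arrays 3 and 4 against 0.18 with them, so their shift may come from the higher top signals of these arrays. For the acute phase list the genotype, and inflammation of unknown origin in these mice, stay open and were not tested.

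Prtn3 was higher in the transgenic mice, at a signal of 604 against 19.4 in wild-type mice on the high-fat diet, the latter under the limit for dim probe sets. Neutrophils or their precursors in the samples stay open: the median log2 change of 12 other neutrophil markers, with Lcn2 left out because hepatocytes also make it, was 0.21, but 11 of the 12 were dim in wild-type mice, where a change cannot be measured well. Of them, S100a8 (1.41) and S100a9 (1.20) were higher at an unadjusted limma p under 0.05, while Mpo was at 0.029 and Elane at 0.18. Of the 20 nearest measured genes, 4 had an unadjusted p under 0.05 (20% against 13.7% of all genes, exact one-sided binomial p = 0.290), so a changed chromosome segment cannot be told apart from none with so few neighbours. Transcription of Prtn3 in liver cells of transgenic mice was not tested and stays open too.

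Cell cycle genes were higher in the transgenic mice by a mean log2 of 0.96 (camera adjusted p = 0.111 with an estimated correlation). Without transgenic arrays 3 and 4 the shift was 0.79 and the list passed camera with its preset correlation, which argues against their higher top signals as the whole cause. A lower share of hepatocytes, with all other cells gaining alike, would raise stellate and bile duct markers too. Stellate markers were at -0.0069 (upper 95% bound 0.46) and bile duct markers at -0.30, below the lower bound of 0.55 for the cell cycle list. Kupffer markers were at 0.45 (upper 95% bound 1.23), endothelial markers at 0.17 (0.41) and lymphocyte markers at 0.10 (0.69). A gain of particular other cells is therefore not argued against. Which cells carried the cell cycle transcripts was not tested and stays open, as does the genotype.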

How the results depend on the processing

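The fits without transgenic arrays 3 and 4 and without arrays 1 and 2 were chosen after seeing the data. Quantile normalization, log2(signal + 32), the 60% filter and robust eBayes left the counts of called genes within 1.5 times, and the first 3 also the counts of lists. All 29 genes of the Akt1 comparison and 144 of the 165 of transgenic mice against the normal diet were also called after quantile normalization. Without a filter 12 genes passed for Akt1, and with all probe sets 57 for Akt1 and 253 for transgenic mice against the normal diet. Without an intensity trend the counts of genes in these comparisons were 0 and 81, and with only the groups compared in the fit 8 and 104. With array weights 1 gene passed for diet and 58 for Akt1. Without transgenic arrays 3 and 4 the counts were 4 and 23, and without arrays 1 and 2 they were 158 and 348. With arrays 1 and 2 alone as the transgenic group, all 29 genes kept their direction and an unadjusted p under 0.05, at a median of 89.2% of the change, but 1 of the 29 was called. The 29 genes were chosen in a fit that held these same arrays, so the kept direction is no independent support. The number of arrays was not separated from which arrays were kept, and the cause of the moves in the counts was not tested. With an estimated correlation 0 lists passed for diet and 0 for Akt1, and by fry 0 and 4.

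The correlation of fold changes was -0.345 without a filter, -0.0342 with the 60% filter and 0.124 with the shared arrays split. The split removes the negative term that shared arrays add. Deviations shared by same-numbered arrays could also make the split value positive, so no direction is read from it. Leaving out one array at a time gave 0 to 2 genes for diet, 0 to 64 for Akt1, 36 to 162 for transgenic mice against the normal diet, 4 to 9 lists for diet, 15 to 17 lists for Akt1, correlations of -0.255 to -0.101, and 0 genes moved back.

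Same-numbered arrays did not deviate together throughout. Correlations of their deviations were -0.0721 to 0.0287 for diet, 0.0842 to 0.292 for Akt1 and -0.0592 to 0.111 for the third comparison, so the numbers were not taken as pairs, although 4 of 4 transgenic arrays correlated best with the wild-type high-fat array of their own number. With the replicate number as a block, 2 genes passed for diet, 31 for Akt1 and 139 for transgenic mice against the normal diet, with 9 lists for diet (interferon response and xenobiotic metabolism gained) and 15 for Akt1, a correlation of -0.140 and 1 gene moved back.

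Some lists shifted differently between transgenic arrays, and the cause was not tested. The fits without some transgenic arrays kept all 4 wild-type high-fat arrays, so replicate numbers were no longer balanced between the groups. Wild-type high-fat arrays differed as well, with peroxisomal PPARA scores of -0.65 in array 2 and 0.20 in array 3. Deviations shared by same-numbered arrays could therefore contribute to the shifts given here. Without transgenic arrays 3 and 4, mitochondrial fatty acid oxidation shifted by -0.18 (0.096 with all), heat shock and immediate early genes by -0.28 (0.061 with all) and peroxisomal PPARA targets by -0.41. Without arrays 1 and 2 these were at 0.37, 0.41 and 0.50, the last with a mean of 0.046 over all arrays and no direction in camera (adjusted p = 0.976). Values for single genes and lists were also counted under the other settings, those that left out named arrays aside. Of these, 656 and 367 stayed on their side of the threshold, though values that passed in neither fit may have changed direction. These totals include values that did not pass in the main fit, among them all named genes for diet. Only values that had passed could be lost, so the totals do not give the share of calls that held. Another 59 and 41 kept their direction but no longer passed, and 3 and 8 newly passed. The fits with only the groups compared are included. Signal over background was not available here, so dim genes could not be judged on it.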

Other observations

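The genes of the first 2 paragraphs, apart from Me1, were chosen after their values were seen. Genes of insulin and growth hormone signalling went both ways in the transgenic mice and did not pass as a list (camera adjusted p = 0.668). Of 33 measured genes, 2 were higher and 2 lower when adjusted over the list alone, and none passed over all genes. Against wild-type mice on the high-fat diet, Socs3, an inhibitor of cytokine and growth hormone signalling, was at 2.21 ± 0.48 (log2, SE) and the growth factor binding protein gene Igfbp2 at 1.08 ± 0.21. The growth hormone receptor gene Ghr was at -0.39 ± 0.09 and the kinase subunit gene Pik3r1 at -0.85 ± 0.21. Against wild-type mice on the normal diet, Socs3 (2.40 ± 0.52, limma adjusted p = 0.0413) and Igfbp2 (1.09 ± 0.23, 0.0377) rose over all genes tested.

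In transgenic mice against wild-type mice on the normal diet, the fatty acid synthesis list shifted by -0.42 in camera (adjusted p = 0.0151, and adjusted p = 0.461 with an estimated correlation), with 4 of 21 genes lower and 1 higher when adjusted over the list alone. Cholesterol synthesis and uptake shifted by -0.51 (camera adjusted p = 0.000198, and adjusted p = 0.461 with an estimated correlation), with 6 of 20 lower when adjusted over the list alone. In the fatty acid synthesis list the desaturase Fads2 rose by 1.11 ± 0.22 (limma adjusted p = 0.0298) and Me1 fell by 2.37, while Fasn was at -1.94 ± 0.61 (limma adjusted p = 0.126) and Scd1 at -1.27 ± 0.34 (0.0824). Among Kupffer cell and macrophage markers, Cd5l (2.02 ± 0.46) and Folr2 (1.53 ± 0.34) rose in that comparison, and 13 of 18 were higher when adjusted over the list alone.

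Oxidation genes differed between mice of one group. The score of peroxisomal and microsomal PPARA targets was -0.28, -0.77, 0.68 and 0.077 in transgenic arrays 1, 2, 3 and 4, and -0.0043, -0.65, 0.20 and -0.018 in wild-type high-fat arrays 1, 2, 3 and 4, where 0 is the normal-diet mean.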
